A study of Homo sapiens with 8 samples.

How the data were processed

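RNA levels were measured on 8 one-colour Affymetrix arrays, 1 array per sample, each with 54675 probe sets. Per the labels, total RNA was taken from 2 breast cancer cell lines infected with a lentivirus carrying a control hairpin (shCtrl) or a hairpin against XBP1 (shXBP1) and held for 24 h in 0.1% O2 in medium without glucose. The 4 groups of cell line and hairpin hold 2 arrays each. Group and replicate number were taken from the labels, which call the replicates biological. Nothing says whether the replicates were separate infections or cultures, so p-values measure only the spread between these samples, which may be technical. The untreated conditions named in the study design were not analysed here.

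The authors deposited 1 table of log2 expression values per probe set, and the submitters' processing notes name RMA and the affy package, version 1.30.0. RMA subtracts background, normalizes arrays by quantiles and summarises the probes of each probe set on a log2 scale. Which arrays were normalized together is not given in the sources used here. The deposited log2 values ran from 2.75 to 15.6, and the medians of the 8 arrays lay between 5.87 and 5.91. Replicate arrays correlated at 0.996 to 0.998 across the 19775 genes tested, each at its brightest probe set, and no pair was identical. The values were used as deposited, with no further normalization. They carry no detection calls, and RMA compresses folds against dim levels, so a fold against a level near or under the median of all probe sets (5.96) understates the change.

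Probe sets were named through the table of probe sets and genes supplied for this array. It listed 42898 probe sets, of which 1801 carried several gene symbols and were not used, and 41091 probe sets with 1 symbol each entered the gene tests. A further 11721 probe sets were unnamed here and 62 were control probe sets. Symbols were compared with the RefSeq gene table by gene identifier, which changed 0 symbols and left 54 identifiers without a match. Each gene was represented by its single-symbol probe set with the highest mean over the 8 arrays, giving 19775 genes. No filter on dim genes and no minimum fold was applied.

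Tests were run in R 4.3.3 with limma 3.58.1 (lmFit and eBayes). The 4 group means were fitted together with 1 shared spread per gene, because 2 arrays per group leave only 4 residual degrees of freedom (7.62 after moderation). The contrasts were shXBP1 against shCtrl in each line, the difference of these 2 effects (the MDA-MB-231 effect minus the T47D effect), and MDA-MB-231 shCtrl against T47D shCtrl. All tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested, and genes with an adjusted p under 0.05 were called changed. An exact permutation test of 2 against 2 arrays cannot give a p below 0.333, so the model across all genes was used. The number of arrays limits the precision, and the median standard error of a knockdown fold change was 0.119 on the log2 scale (0.168 for the difference between the lines).

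The analysis was tested on simulated arrays with 19775 genes and noise drawn independently for each gene. Log2 changes of 0.5, 1 and 2 were planted in 67, 67 and 66 genes per line. With a planted log2 change of 1, 97.0% of changed genes were recovered in the T47D comparison and 95.5% in the MDA-MB-231 comparison. With a planted change of 0.5 these shares were 32.8% and 29.9%, and with a change of 2 both were 100%. Of all calls, 7.27% (T47D) and 3.85% (MDA-MB-231) were false. In the real arrays 29.1% (T47D) and 17.2% (MDA-MB-231) of genes were called, and genes are not independent. The simulated shares therefore need not hold there.

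The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Further alternatives for the overlap and the gene lists were chosen after seeing the data. The rule named XBP1, then the 10 largest rises and 10 largest falls per knockdown comparison among changed genes whose shXBP1 arrays both lay on the same side of both shCtrl arrays. For the difference between the lines and for the comparison of the lines it named the 8 largest each way. For each gene list it named up to 4 changed members with the largest fold changes or, where none changed, up to 2 with the smallest p. VEGFA, PDK1, SLC2A1, KDM3A, DDIT4, CA9, HSPA5, DNAJB9, DDIT3 and HIF1A were always to be given. CA9 had no probe set with a single symbol in the annotation used here and is not reported. Of the genes the rule named, those given in the text are a part, and other genes are named only where stated.

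Of the 22 gene lists tested, 1 is not described here, although the counts over all list tests include it, and the others covered ER translocation and signal peptide cleavage, ER chaperones and folding enzymes, ER-associated degradation, ER to Golgi transport, N-glycosylation, substrates of IRE1-dependent decay, PERK and ATF4 targets, HIF1 targets, sterol and fatty acid synthesis, luminal and oestrogen receptor genes, mesenchymal and basal B genes, cell proliferation, interferon response, NF-kB and inflammatory cytokines, oxidative phosphorylation, cytosolic ribosomal proteins, cytosolic heat shock response, autophagy and lysosome, immediate early genes, and markers of leukocytes and of fibroblasts. The lists were written from general knowledge, and 6 genes stand in 2 lists. Each list was tested with camera (limma) at a preset correlation of 0.01 between genes, adjusted over 88 tests (22 lists in 4 contrasts). Of these, 32 passed, and with the correlation estimated from the arrays 1 passed, the luminal list between the lines. That version also rests on the 4 residual degrees of freedom, so its losses are not those of the correlation alone. For immediate early genes, for example, the estimate was -0.0257, under the preset value, and their knockdown calls were still lost. The fry test, which asks whether the genes of a list move on balance one way without comparing them with other genes, passed for 71, and its mixed version, for changes in either direction, passed for 85. The list median, mean and test differed in sign in 8 of the 88 tests, and in 0 of those that passed. Counts of changed members were also taken with p-values adjusted over the list alone.

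Alternatives were the mean over the probe sets of a gene, each probe set tested on its own, 2 filters on dim genes, quantile normalization applied again, centring each array on its median, a spread model with trend and robust fitting, a fit on the 4 arrays of a line only, array weights, a minimum absolute log2 fold change of 1, and leaving out each array in turn. Where an array was left out, the lone array of its group was assumed to vary like the others. Gene families grouped by symbol stem, and some comparisons in the closing observations, were added after the data were seen.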

Results

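Expression was profiled in T47D, a luminal, oestrogen receptor-positive breast cancer line, and in MDA-MB-231, a triple-negative line with mesenchymal features. All 8 samples came from cells kept in hypoxia without glucose, with a control hairpin or a hairpin against XBP1, at 2 arrays per group. XBP1 encodes a transcription factor of the unfolded protein response whose mRNA is spliced by the ER sensor IRE1. The comparisons ask which transcripts depend on XBP1 under this combined stress, and whether the 2 lines respond alike. All changes below are log2 fold changes of shXBP1 against shCtrl unless stated, with limma standard errors (SE) and adjusted p-values.

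XBP1 itself fell in both lines. In T47D its level went from 12.49 ± 0.10 (SD, n = 2) with shCtrl to 7.34 ± 0.26 with shXBP1, a change of -5.15 (SE 0.17, adjusted p = 8.68e-06) or 35.4-fold. In MDA-MB-231 it went from 10.76 ± 0.10 to 6.91 ± 0.31, a change of -3.85 (SE 0.17, adjusted p = 6.93e-05) or 14.4-fold. The fall was smaller in MDA-MB-231 by 1.296 (SE 0.25, adjusted p = 0.00745), where the starting level was lower. These values come from the brightest XBP1 probe set. A second one read between 5.51 and 6.37 on all 8 arrays, near the median of all probe sets, and did not change (-0.23 in T47D, adjusted p = 0.320, and 0.19 in MDA-MB-231, adjusted p = 0.459). The mean over the XBP1 probe sets, which includes the dim one, was -2.69 in T47D and -1.83 in MDA-MB-231.

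**Figure D1:**
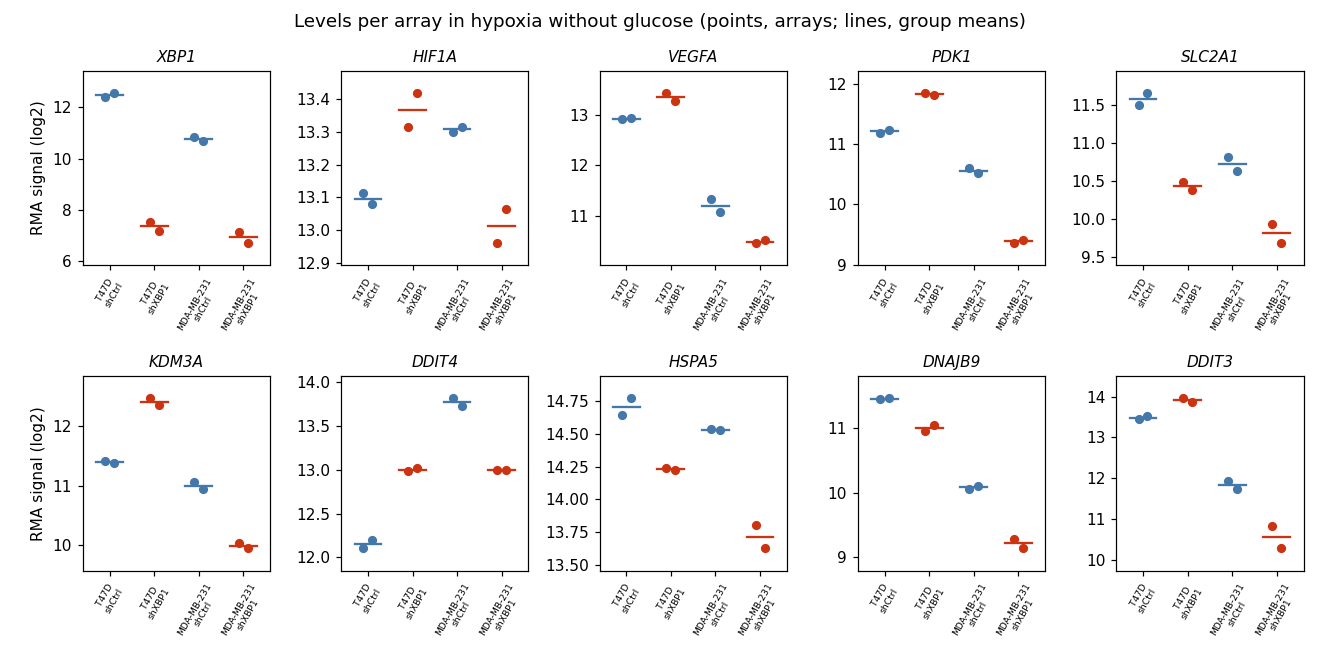
RMA signal (log2) of XBP1 and 9 genes of the hypoxia and ER stress responses on each array, with points for arrays and lines for the means of the 4 groups of 2 arrays. XBP1 was lower on the shXBP1 arrays of both lines, while VEGFA, PDK1, KDM3A and DDIT4 were higher with shXBP1 in T47D and lower in MDA-MB-231.

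In T47D, XBP1 knockdown changed 5746 of 19775 genes, 3071 up and 2675 down, and 767 rose and 468 fell by at least 2-fold. The largest rises were CRISP3, a secreted cysteine-rich protein (22.3-fold, log2 4.48, SE 0.33, adjusted p = 7.52e-05), and EPB41L3, which links membrane proteins to the cytoskeleton (17.6-fold, SE 0.11, adjusted p = 7.51e-06). KLF3, a transcriptional repressor, and EREG, a ligand of the EGF receptor, each rose by 3.46 on the log2 scale. The Wnt receptor gene FZD5 rose 9.66-fold, RASGRP1 9.50-fold, CFHR4 9.20-fold, the matrix proteoglycan gene VCAN 9.09-fold, NACC2 8.60-fold and CPEB2 8.55-fold. The largest falls after XBP1 were CGA, the common subunit of the glycoprotein hormones (22.9-fold lower, SE 0.22, adjusted p = 1.90e-05), LRRC15 (21.5-fold lower) and VTCN1, an inhibitory ligand of T cells (13.4-fold lower). HSD17B1, which converts estrone to estradiol, was 12.6-fold lower, TOP2A, the DNA topoisomerase of dividing cells, 8.60-fold lower, PLAC8 6.50-fold lower, EDN2 6.27-fold lower and RAB31 6.20-fold lower. CHP1 was 6.50-fold lower, but another of its probe sets rose. With the mean over probe sets, changes of several of these genes were smaller by over 1.5 times on the log2 scale: KLF3 (2.28), EREG (1.84), NACC2 (1.79), CPEB2 (1.29), CGA (-2.24), LRRC15 (-2.16), HSD17B1 (-2.10) and CHP1 (-0.995).

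Genes of the secretory pathway fell in T47D. Of 20 measured genes of ER-associated degradation, 8 fell, 1 rose and 11 did not pass (9 and 1 adjusted over the list alone), with EDEM2 at -1.01 (SE 0.10), SELENOS at -0.98 and OS9 at -0.76. The list was lower (median -0.24, camera adjusted p = 0.00367, adjusted p = 0.271 with an estimated correlation). Of 32 N-glycosylation genes 18 fell and 2 rose, and the same numbers passed when adjusted over the list alone, among them DPAGT1, the first enzyme of the lipid-linked oligosaccharide pathway (-1.21, SE 0.11), and DPM3 (-0.97). That list had a median of -0.35 (adjusted p = 0.000217, adjusted p = 0.331 with an estimated correlation). In ER to Golgi transport 10 of 32 fell and 1 rose (10 and 2 adjusted over the list alone), led by the KDEL receptor gene KDELR3 (-1.35, SE 0.16), PREB (-1.01) and COPG1 (-0.89). Its list p was 0.0229 (adjusted p = 0.331 with an estimated correlation). Of 23 ER chaperones and folding enzymes 8 fell and 2 rose (9 and 2 adjusted over the list alone), including SDF2L1 (-0.95, SE 0.09), DNAJC10 (-0.73), CRELD2 (-0.67) and HYOU1 (-0.61). The chaperone list had a p of 0.0376 (adjusted p = 0.514 with an estimated correlation). The chaperone list no longer passed without T47D shCtrl replicate 2 (0.0841), without T47D shXBP1 replicate 2 (0.0847) with either filter on dim genes (0.0702 and 0.0654) or with quantile normalization applied again (0.117). The transport list did not pass with the latter (0.0890).

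Among genes that move proteins into the ER, 8 of 22 fell and 3 rose in T47D (10 and 3 adjusted over the list alone), such as SEC11C at -0.78 and SRPRA at 0.87, and the list test gave an adjusted p of 0.248. Of 10 substrates of IRE1-dependent decay, 3 fell and 2 rose (4 and 2 adjusted over the list alone, list adjusted p = 0.392), and TAPBP was at 1.06 (SE 0.10). HSPA5, which encodes the main ER chaperone BiP, fell by 0.47 (SE 0.10, adjusted p = 0.00782) and its co-chaperone DNAJB9 fell by 0.46 (SE 0.09, adjusted p = 0.00749). With the mean over probe sets HSPA5 was at -1.28. The HSPA5 call was lost without T47D shCtrl replicate 2 (adjusted p = 0.0545) or shXBP1 replicate 2 (0.0524), and the DNAJB9 call without T47D shXBP1 replicate 1 (0.0647).

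Growth and metabolic genes were also lower in T47D. Of 33 proliferation genes 28 fell (29 adjusted over the list alone), including TOP2A at -3.10 (SE 0.12), the ribonucleotide reductase gene RRM2 at -2.01, CDC6 at -1.37 and MCM3 at -1.15. The list median was -0.63, with a camera adjusted p of 4.52e-13 (adjusted p = 0.307 with an estimated correlation). Of 33 oxidative phosphorylation genes 20 fell (22 adjusted over the list alone), with smaller changes such as ATP5F1A at -0.77 and NDUFV2 at -0.68. That list had a median of -0.30 and an adjusted p of 9.80e-07 (adjusted p = 0.331 with an estimated correlation). In sterol and fatty acid synthesis 14 of 23 fell and 3 rose (17 and 3 adjusted over the list alone), with ACLY at -1.33 (SE 0.08) and FASN, the fatty acid synthase gene, at -1.01. The synthesis list had a p of 0.000217 (adjusted p = 0.331 with an estimated correlation). Of 25 autophagy and lysosome genes 9 fell and 6 rose, the same numbers as adjusted over the list alone, for example LAMP2 at -1.10 and HEXA at 1.00, and the list did not pass (adjusted p = 0.407).

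Several stress and signalling lists were higher in T47D. Of 30 PERK and ATF4 targets 13 rose and 3 fell (15 and 3 adjusted over the list alone), with PSPH, of serine synthesis, at 1.49 (SE 0.10), SESN2 at 1.48 and ATF3 at 1.40 against the cystathionine lyase gene CTH at -1.75. The PERK list had a p of 0.00283 (adjusted p = 0.514 with an estimated correlation). Of 21 immediate early genes 11 rose and 3 fell (12 and 3 adjusted over the list alone), with ZFP36 and KLF4 at 2.01 each and NR4A3 at -1.98. Their list p was 0.00283 (adjusted p = 0.271 with an estimated correlation). Of 26 NF-kB genes and inflammatory cytokines 9 rose and 2 fell, as they did adjusted over the list alone, including TNFAIP3 at 1.04 (SE 0.11) and RELB at 0.79. The NF-kB list had a p of 0.0309 (adjusted p = 0.307 with an estimated correlation) that rose to 0.0717 without T47D shXBP1 replicate 2 and to 0.126 and 0.0869 with the filters on dim genes. DDIT3, the ER stress gene encoding CHOP, had a value of 0.42 (adjusted p = 0.106), and passed with only the T47D arrays in the fit (adjusted p = 0.0162).

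The hypoxia genes of T47D went both ways. Of 44 HIF1 targets 10 rose, 12 fell and 22 did not pass (10 and 13 adjusted over the list alone), and the list test gave an adjusted p of 0.713. PDK1, a kinase that inhibits pyruvate dehydrogenase, rose by 0.62 (SE 0.08, adjusted p = 0.00110), the histone demethylase gene KDM3A by 1.01 (SE 0.09, adjusted p = 0.000183), DDIT4, an inhibitor of mTOR signalling, by 0.85 (SE 0.09, adjusted p = 0.000287), PFKFB4 by 1.51 and ADM by 1.15. The glucose transporter genes SLC2A1 and SLC2A3 fell by 1.15 (SE 0.12, adjusted p = 0.000355) and 2.01, and ANGPTL4 fell by 1.63. VEGFA rose by 0.42 (SE 0.11, adjusted p = 0.0222), a call lost at similar values without T47D shCtrl replicate 1 (0.41, adjusted p = 0.0961), shCtrl replicate 2 (0.44, 0.0795) or shXBP1 replicate 1 (0.34, 0.148). KDM3A was at 0.63 and SLC2A3 at -1.27 with the mean over probe sets. HIF1A mRNA had a value of 0.27 (SE 0.09, adjusted p = 0.0538), which passed when dim genes were left out (adjusted p = 0.0221).

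Of the remaining lists described here, only that of ribosomal proteins passed in T47D. Of 30 luminal genes 7 rose and 8 fell (8 and 8 adjusted over the list alone), with AGR3 at 1.15, TFF1 at -1.60 and KRT8 at -1.33 (list adjusted p = 0.714). Of 30 mesenchymal genes 5 rose and 6 fell, also adjusted over the list alone, with the annexin gene ANXA1 at 2.71 and CCN2 at -2.58 (list adjusted p = 0.755). Of 28 interferon response genes 7 rose and 2 fell (8 and 2 adjusted over the list alone), with OAS1 at 1.06 and IFIT1 at 1.00 (list adjusted p = 0.124). In the heat shock list 3 of 17 rose and 1 fell, also adjusted over the list alone, and HSPB8 was at 1.46 (list adjusted p = 0.965). Of 33 cytosolic ribosomal protein genes 0 passed limma's test, also adjusted over the list alone, and 4 had an unadjusted p under 0.05. Their median was 0.11 with a camera adjusted p of 0.0376 (adjusted p = 0.514 with an estimated correlation), which was not under 0.05 without any 1 of the 4 T47D arrays (0.0866 and 0.0649 without shCtrl replicates 1 and 2, 0.0671 and 0.0893 without shXBP1 replicates 1 and 2). It was also lost with the filters on dim genes (0.0672 and 0.0737), the mean over probe sets (0.251) and quantile normalization applied again (0.117). Of 13 leukocyte markers 0 passed in limma, in all and adjusted over the list alone, and 0 had an unadjusted p under 0.05 (list adjusted p = 0.903). Of 13 fibroblast markers 1 rose and 3 fell, also adjusted over the list alone, with COL5A1 at -1.71 (list adjusted p = 0.278). Among the list members named for T47D, the mean over probe sets gave smaller changes for FASN (-0.50), HEXA (0.49), TAPBP (0.63), SEC11C (-0.48), NR4A3 (-1.07), PFKFB4 (1.002) and COL5A1 (-0.50).

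**Figure D2:**
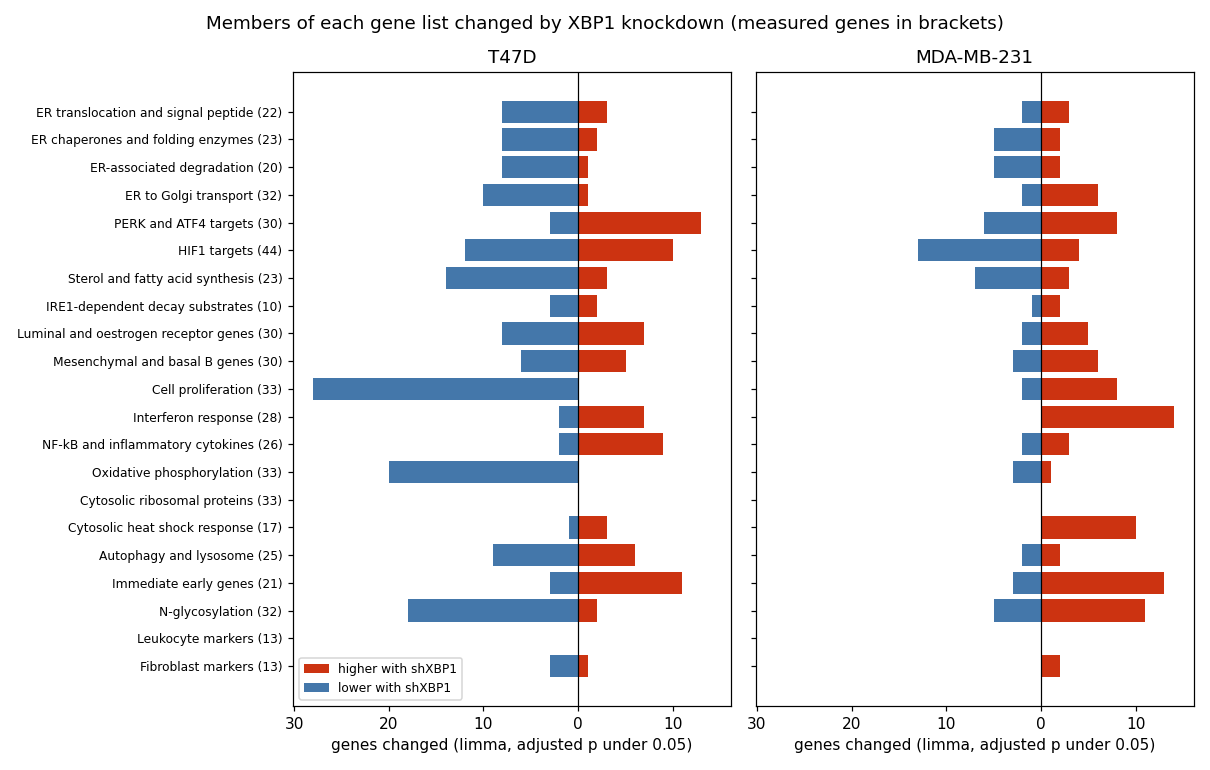
Number of genes of each gene list described here that were higher (right of 0) or lower (left of 0) with shXBP1 at an adjusted p under 0.05, for T47D and MDA-MB-231, with the number of measured genes in brackets. In T47D 28 of 33 proliferation genes were lower, and in MDA-MB-231 14 of 28 interferon response genes were higher.

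In MDA-MB-231, XBP1 knockdown changed 3410 genes, 2090 up and 1320 down, and 374 rose and 136 fell by at least 2-fold. The chemokine gene CCL5 rose most, 29.2-fold (log2 4.87, SE 0.15, adjusted p = 1.92e-05), followed by HSPA6, an inducible HSP70 gene, at 21.8-fold with a wider error (log2 4.44, SE 0.50, adjusted p = 0.00115). RASD1 rose 12.4-fold, the water and glycerol channel gene AQP3 11.6-fold, HSPA2 11.4-fold, MFAP5 10.8-fold and GEM 10.5-fold. MLKL, the effector of necroptosis, rose 9.88-fold, the cytokine receptor gene IL7R 8.70-fold and GBP3 8.26-fold. After XBP1 the largest falls were ZNF292 (5.98-fold lower, SE 0.12, adjusted p = 7.19e-05), the cyclin gene CCNG2 (5.24-fold lower), AXL, a receptor tyrosine kinase (4.58-fold lower, SE 0.34), the cytokine gene IL20 (4.49-fold lower), the linker histone gene H1-4 (4.45-fold lower) and PPP1R3B (3.82-fold lower). AKAP11, KLF9 and XK were 3.77-fold, 3.70-fold and 3.48-fold lower, and DOCK5 was 3.53-fold lower although another of its probe sets rose. The number of changed genes was 2063 without MDA-MB-231 shCtrl replicate 1, 2152 without MDA-MB-231 shXBP1 replicate 1 and 1897 with only the 4 arrays of this line in the fit. Of the calls, 61.3% were higher over genes, but 46.9% were higher when each probe set was tested on its own. The mean over probe sets gave smaller changes for AQP3 (2.32), ZNF292 (-1.35), CCNG2 (-1.36), AXL (-1.13), PPP1R3B (-1.10), AKAP11 (-1.14), KLF9 (-0.71) and DOCK5 (-0.92). The ACTB difference between 3' and 5' probe sets, a measure of RNA quality, averaged 1.256 on the shCtrl and 0.999 on the shXBP1 arrays of this line, while that of GAPDH averaged 0.302 and 0.312, and its bearing on the changes was not tested.

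Heat shock, interferon and immediate early genes rose in MDA-MB-231. Of 17 cytosolic heat shock genes 10 rose (13 adjusted over the list alone), with HSPA6 above, HSPB8 at 1.96 (SE 0.12), CRYAB at 1.81 and DNAJB4 at 1.80. The heat shock list had a p of 9.80e-07 (adjusted p = 0.307 with an estimated correlation). Of 28 interferon response genes 14 rose, as they did adjusted over the list alone, and 14 did not pass. IFIT1 was at 2.52 (SE 0.13), IFIT2 at 2.39, IFIT3 at 2.35 and OASL at 2.34, and the list median was 0.38 (0.63 with dim genes left out) with a camera adjusted p of 1.38e-06 (adjusted p = 0.271 with an estimated correlation). Of 21 immediate early genes 13 rose and 3 fell (14 and 3 adjusted over the list alone), with IER5 at 2.63, EGR1 at 2.04 and FOSB at 2.00. Their list p was 0.000501 (adjusted p = 0.271 with an estimated correlation). Of 26 NF-kB genes and cytokines 3 rose and 2 fell, also adjusted over the list alone, with IL6 at 1.41 and CXCL8 at -1.01 (list adjusted p = 0.596). Of 13 leukocyte markers 0 passed in limma, also adjusted over the list alone, and 2 had an unadjusted p under 0.05, with CD14 at 0.75 (adjusted p = 0.107) and NKG7 at -0.37 (adjusted p = 0.0702). CD14 passed with trend and robust fitting (adjusted p = 0.0394) and without MDA-MB-231 shXBP1 replicate 2 (1.106, adjusted p = 0.0480), with a lowest value of 0.404 without shXBP1 replicate 1, and NKG7 without T47D shCtrl replicate 1 or 2 (adjusted p = 0.0433 each).

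Hypoxia genes fell in this line. Of 44 HIF1 targets 13 fell and 4 rose (16 and 5 adjusted over the list alone), with a list median of -0.15 and an adjusted p of 0.000217 (adjusted p = 0.514 with an estimated correlation). PDK1 fell by 1.17 (SE 0.08, adjusted p = 0.000213), PFKFB3 by 1.11 (SE 0.10), HK2, a hexokinase gene, by 1.02 (SE 0.12), KDM3A by 1.01 (SE 0.09, adjusted p = 0.000505), DDIT4 by 0.78 (SE 0.09, adjusted p = 0.00110) and VEGFA by 0.71 (SE 0.11, adjusted p = 0.00445). SLC2A1 fell by 0.91 (SE 0.12, adjusted p = 0.00249), but its mean over probe sets gave -0.35 (adjusted p = 0.158). HIF1A mRNA had a value of -0.30 (SE 0.09, adjusted p = 0.0575), and passed when dim genes were left out (adjusted p = 0.0236).

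ER chaperone genes fell in MDA-MB-231 as well, while other secretory genes went both ways. Of 23 chaperones and folding enzymes 5 fell and 2 rose (8 and 2 adjusted over the list alone), with SDF2L1 at -0.90 (SE 0.09), DNAJB9 at -0.87 (SE 0.09, adjusted p = 0.000928) and HSPA5 at -0.82 (SE 0.10, adjusted p = 0.00145) against SIL1 at 0.70. The chaperone list had a p of 0.00973 (adjusted p = 0.514 with an estimated correlation). Of 30 PERK and ATF4 targets 8 rose and 6 fell (10 and 8 adjusted over the list alone, list adjusted p = 0.920), with DDIT3 at -1.29 (SE 0.17, adjusted p = 0.00227), SESN2 at -1.19 and STC2 at 0.98. Of 20 genes of ER-associated degradation 5 fell and 2 rose (6 and 3 adjusted over the list alone), with UBXN4 at -1.14 and RNF139 at -1.01 (list adjusted p = 0.0739). In ER to Golgi transport 6 of 32 rose and 2 fell, also adjusted over the list alone, with SEC23B at 1.53 and SEC31A at 1.04 (list adjusted p = 0.179). Of 32 N-glycosylation genes 11 rose and 5 fell (12 and 6 adjusted over the list alone), with ALG2 at 0.92 and DPM1 at 0.88 (list adjusted p = 0.0876). In ER translocation 3 of 22 rose and 2 fell (4 and 2 adjusted over the list alone), with SRP72 at -0.66 (list adjusted p = 0.432). Of 10 substrates of IRE1-dependent decay 2 rose and 1 fell, also adjusted over the list alone, with SCARA3 at 0.79 (list adjusted p = 0.693).

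Proliferation genes did not move one way in MDA-MB-231: 8 of 33 rose and 2 fell (11 and 3 adjusted over the list alone, list adjusted p = 0.432), with UBE2C at 1.77 (SE 0.09), AURKA at 0.72 and TOP2A at -1.72 (SE 0.12). In sterol and fatty acid synthesis 7 of 23 fell and 3 rose (9 and 3 adjusted over the list alone), with ACLY at -0.78 and ELOVL6 at 1.11. The list p was 0.0306 (adjusted p = 0.514 with an estimated correlation). Without MDA-MB-231 shCtrl replicate 2 that list p was 0.0747, without shXBP1 replicate 1 it was 0.0858, and with the filter at the median level 0.0512. Of 33 oxidative phosphorylation genes 3 fell and 1 rose (1 and 1 adjusted over the list alone), and NDUFB3, which rose, was at 0.62. As a whole the list was lower, with a median of -0.11 and negative values for 25 of the 33. The oxidative phosphorylation list had a p of 0.0150 (adjusted p = 0.514 with an estimated correlation) that was 0.0747 without MDA-MB-231 shCtrl replicate 2 and 0.0733 without shXBP1 replicate 2. Of 30 luminal genes 5 rose and 2 fell (8 and 3 adjusted over the list alone), with NAT1 at 2.19 and ELF3 at 1.24 (list adjusted p = 0.303). Of 30 mesenchymal genes 6 rose and 3 fell, also adjusted over the list alone, with the fibronectin gene FN1 at 2.66 (list adjusted p = 0.471). Of 25 autophagy and lysosome genes 2 rose and 2 fell (3 and 2 adjusted over the list alone), with the cathepsin gene CTSB at 0.92 (list adjusted p = 0.296). Of 33 ribosomal protein genes 0 passed in limma, also adjusted over the list alone, and 0 had an unadjusted p under 0.05 (list adjusted p = 0.693). Of 13 fibroblast markers 2 rose, also adjusted over the list alone, with FAP at 1.60 and ACTA2 at 0.94 (list adjusted p = 0.303). Among the list members named for this line, the mean over probe sets gave smaller changes for HK2 (-0.48), FN1 (1.69), ALG2 (0.54), SRP72 (-0.33), UBXN4 (-0.59) and ACTA2 (0.43).

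The effect of the knockdown differed between the lines for 4905 genes, 2579 with a higher and 2326 with a lower log2 fold change in MDA-MB-231 than in T47D. Tested over single probe sets the balance turned, with 4387 higher and 5504 lower. The difference was largest for AQP3, which fell in T47D (from 8.57 to 6.58) and rose in MDA-MB-231 (from 8.35 to 11.88), a difference of 5.52 (SE 0.19, adjusted p = 4.61e-05). CCL5 (4.81), HSPA6 (4.53, SE 0.71), MFAP5 (3.62) and CCN5 (3.33) were raised relative to T47D, and CGA (4.54), LRRC15 (4.48) and VTCN1 (3.76) fell in T47D from levels above those of MDA-MB-231, where their knockdown values were 0.03, 0.06 and 0.02. CRISP3 (-4.55), EPB41L3 (-3.99), RASGRP1 (-3.66), FZD5 (-3.47), CPEB2 (-3.46), ZNF292 (-3.46), PSD3 (-3.34) and EREG (-3.33) had the most negative differences. With the mean over probe sets the differences were smaller for AQP3 (3.17), CGA (2.18), LRRC15 (2.20), FZD5 (-2.18), CPEB2 (-1.51), ZNF292 (-2.11), EREG (-1.71) and XBP1 (0.86).

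Single hypoxia and stress genes differed, while the HIF1 list did not pass as a whole. KDM3A differed by -2.03 (SE 0.13, adjusted p = 0.000141), PDK1 by -1.79 (SE 0.12, adjusted p = 0.000157), DDIT3 by -1.71 (SE 0.24, adjusted p = 0.00194), DDIT4 by -1.63 (SE 0.12, adjusted p = 0.000220) and VEGFA by -1.13 (SE 0.16, adjusted p = 0.00182). HIF1A differed by -0.57 (SE 0.12, adjusted p = 0.0135), which did not pass without T47D shXBP1 replicate 2 (adjusted p = 0.0634). For SLC2A1 (0.24, adjusted p = 0.376), DNAJB9 (-0.42, adjusted p = 0.0542) and HSPA5 (-0.34, adjusted p = 0.111) no difference passed in the fit used here. DNAJB9 passed with the filters on dim genes (adjusted p = 0.0243 and 0.0267), quantile normalization applied again (0.0492), trend and robust fitting (0.00750) and without MDA-MB-231 shXBP1 replicate 1 (0.0434). HSPA5 passed with trend and robust fitting (0.00277), and in the other direction with the mean over its probe sets (0.70, adjusted p = 0.0209), another of its probe sets being called in the opposite direction. Of the 44 HIF1 targets 14 had a lower and 10 a higher change in MDA-MB-231 (16 and 10 adjusted over the list alone, list adjusted p = 0.251).

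Of the other lists, 7 differed between the lines. Proliferation genes had a higher change in MDA-MB-231 for 21 of 33 (23 adjusted over the list alone), with a median difference of 0.91 and an adjusted p of 1.60e-10 (adjusted p = 0.307 with an estimated correlation). N-glycosylation genes did so for 16 of 32, also adjusted over the list alone (adjusted p = 2.72e-05, adjusted p = 0.331 with an estimated correlation). ER to Golgi transport genes did so for 13 of 32 against 3 lower (15 and 3 adjusted over the list alone, adjusted p = 0.00262, adjusted p = 0.307 with an estimated correlation). Heat shock genes had a higher change for 9 of 17 (10 adjusted over the list alone, adjusted p = 0.000557, adjusted p = 0.331 with an estimated correlation). Interferon genes did so for 12 of 28, also adjusted over the list alone (median 0.28, adjusted p = 0.0220, adjusted p = 0.435 with an estimated correlation), with a median of 0.167 without T47D shCtrl replicate 2 and 0.512 with dim genes left out. Oxidative phosphorylation genes did so for 6 of 33 (4 adjusted over the list alone, adjusted p = 0.0192, adjusted p = 0.514 with an estimated correlation). PERK and ATF4 targets had a lower change in MDA-MB-231 for 12 of 30 and a higher one for 6 (14 and 7 adjusted over the list alone, adjusted p = 0.0251, adjusted p = 0.514 with an estimated correlation). The PERK list did not pass without T47D shCtrl replicate 1 (0.0539, with a median of -0.162 against -0.30) or MDA-MB-231 shXBP1 replicate 2 (0.0733), nor with the filters on dim genes (0.0601 and 0.0648). The oxidative phosphorylation list did not pass with the mean over probe sets (0.166) or quantile normalization applied again (0.135), and its median of 0.22 was 0.143 without MDA-MB-231 shXBP1 replicate 1.

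Both knockdown comparisons together changed 1713 genes, of which 1038 moved in the same direction and 675 (39.4%) in opposite directions. The 657 genes that rose in both lines compare with 324.6 for independent lists (odds ratio 2.90, Fisher's exact p = 3.23e-84), and the 381 that fell in both with 178.6 (odds ratio 2.86, p = 4.73e-52). Genes that rose in T47D and fell in MDA-MB-231 numbered 336 (205.0 for independent lists, odds ratio 1.96, Fisher's exact p = 4.81e-22). The reverse held for 339 (282.7, odds ratio 1.27, Fisher's exact p = 0.000197). Over all 19775 genes, opposite changes thus exceeded independent lists too. These genes include dim ones that can hardly be called in either line, which raises all 4 overlaps. The excess of opposite changes is therefore not a result about direction. With the filter at the median level, 1396 of 12701 genes moved the same way and 989 in opposite directions. The overlap of independent lists was not computed for that setting. Genes are not independent of each other and the 2 comparisons share 1 estimate of the spread, so these p-values are too small. ZFP36, HSPB8 and ATF3 rose in both lines, and TOP2A, ACLY and SDF2L1 fell in both. Genes with opposite changes included 7 of the 10 HIF1 targets changed in both lines (VEGFA, PDK1, KDM3A, DDIT4, BNIP3L, HK2 and P4HA2) and 4 of the 8 such PERK and ATF4 targets (SESN2, VLDLR, PPP1R15A and CEBPG). BNIP3L was at 0.42 in T47D and -0.54 in MDA-MB-231, P4HA2 at -0.47 and 0.49, and HK2, for which another probe set differed in the other direction, at 0.86 and -1.02. Across all 19775 genes the log2 fold changes of the lines correlated at r = 0.0993 (Spearman's rho 0.0610), across genes that are not independent replicates. The number of genes changed the same way was 625 without T47D shXBP1 replicate 1, 630 without T47D shXBP1 replicate 2 and 646 with each line fitted on its own arrays. The number changed in opposite directions was 348, 357 and 363 in these 3 settings, 432 and 439 without T47D shCtrl replicates 1 and 2, 386 without MDA-MB-231 shCtrl replicate 1, 415 without MDA-MB-231 shXBP1 replicate 1 and 1100 with trend and robust fitting.

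**Figure D3:**
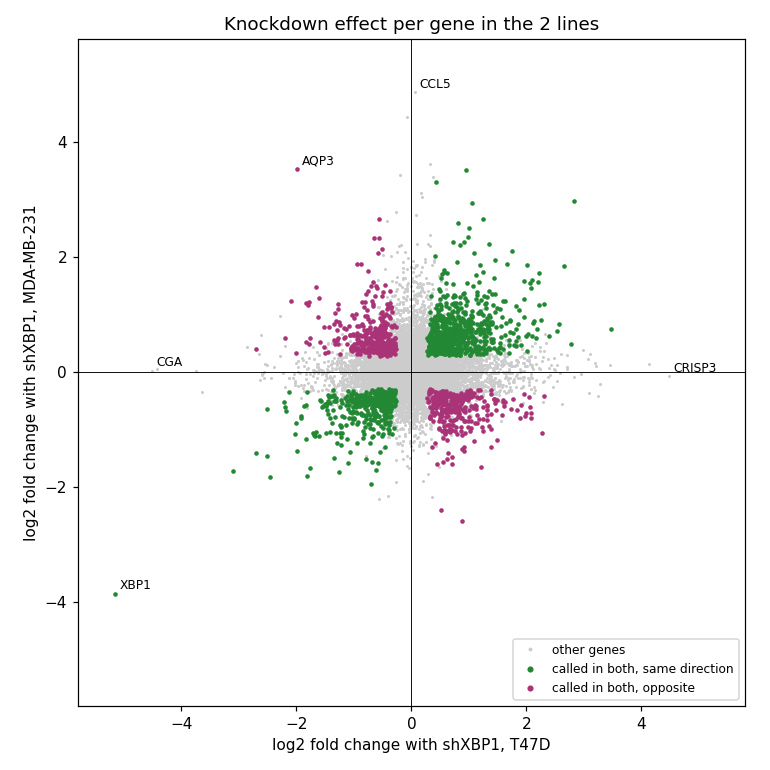
Log2 fold change with shXBP1 in T47D (horizontal) against MDA-MB-231 (vertical) for each of 19775 genes, with genes changed in both lines coloured by whether the directions were the same (1038) or opposite (675). XBP1 lies at -5.15 and -3.85, and AQP3 at -1.99 and 3.53.

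With the control hairpin, the 2 lines differed in 9683 genes, 4692 higher and 4991 lower in MDA-MB-231. Over single probe sets this balance turned, with 11397 higher and 10184 lower. Luminal genes were lower in MDA-MB-231 for 29 of 30 and higher for 1, also adjusted over the list alone, led by the keratin gene KRT19 (log2 difference -10.41, SE 0.10, adjusted p = 4.98e-09), the E-cadherin gene CDH1 (-9.66), the luminal transcription factor gene GATA3 (-9.51) and AGR2 (-8.98). This list passed with the preset correlation (median -5.06, adjusted p = 7.40e-18) and with an estimated one (adjusted p = 0.0449 with an estimated correlation). IGFBP5 (-9.37), DSCAM-AS1 (-9.23), PRLR (-8.85) and PIP (-8.69) were the other large differences in favour of T47D. Of 30 mesenchymal genes 23 were higher in MDA-MB-231 and 3 lower, also adjusted over the list alone, with SNAI2, a repressor of epithelial genes, at 8.65 (SE 0.14) and a list p of 1.49e-09 (adjusted p = 0.197 with an estimated correlation). BASP1 (8.93), WFDC1 (8.82), GPX1 (8.75), TCIM (8.60), LY6K (8.55), CPS1 (8.21) and SGK1 (8.10) were likewise higher in MDA-MB-231. The mean over probe sets gave smaller differences for KRT19 (-5.33), CDH1 (-6.33), IGFBP5 (-4.31), BASP1 (4.80) and LY6K (5.59).

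HIF1 targets and single stress genes also differed between the control arrays of the lines. Of 44 HIF1 targets 26 were lower and 10 higher in MDA-MB-231 (28 and 11 adjusted over the list alone, list adjusted p = 0.00664, adjusted p = 0.514 with an estimated correlation). VEGFA differed by -1.72, SLC2A1 by -0.86 and DDIT4 by 1.62, and among stress genes DDIT3 differed by -1.65 and DNAJB9 by -1.37. PDK1 (-0.65) and KDM3A (-0.40) passed as well, but not with the mean over their probe sets (adjusted p = 0.0719 and 0.660), while HSPA5 (-0.17, adjusted p = 0.188) did not pass and was at -0.77 with that mean (adjusted p = 0.000755). HIF1A did not pass (0.21, adjusted p = 0.0823), but did when dim genes were left out (adjusted p = 0.0386). XBP1 was lower in MDA-MB-231 by 1.73 on the log2 scale (0.77 with the mean over its probe sets). Proliferation genes were higher in MDA-MB-231 for 21 of 33 and lower for 4 (22 and 4 adjusted over the list alone, adjusted p = 0.000487, adjusted p = 0.514 with an estimated correlation). Immediate early genes were higher for 13 of 21 and lower for 4, also adjusted over the list alone (adjusted p = 0.0252, adjusted p = 0.307 with an estimated correlation). NF-kB genes were higher for 13 of 26 and lower for 6, also adjusted over the list alone (adjusted p = 0.0400, adjusted p = 0.329 with an estimated correlation). Without MDA-MB-231 shXBP1 replicate 1 or 2, which enter through the shared spread, the last 2 lists had p-values of 0.0520 and 0.0556 (immediate early) and 0.0569 and 0.0623 (NF-kB). The immediate early list also did not pass with the filter at the median level (0.0513). Poly-A spike-in probe sets read 1.38 higher on the 4 MDA-MB-231 arrays and hybridization spike-in probe sets 0.33 higher (exact permutation p = 0.0286 each, the smallest that 4 against 4 arrays can give), so cell line and array processing cannot be told apart here.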

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

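The tests of exchanged hairpin labels, of a split shared by all changed genes, of leukocytes and of a response to any hairpin were chosen only after the results were seen, and so was the comparison of unnamed probe sets with named ones.

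The knockdown effect differed between the lines for 4905 genes by limma's test of the difference itself. Of 186 genes named in the 2 knockdown comparisons, 145 passed this test, against 24.8% of all genes tested. The naming rule picked them mainly by the size of their change in these same data, which favours a high share. Only the 16 largest differences and those of the genes always given are listed. Relative to T47D the effect in MDA-MB-231 was higher by 5.52 for AQP3, 4.81 for CCL5, 4.54 for CGA, 4.53 for HSPA6, 4.48 for LRRC15, 3.76 for VTCN1, 3.62 for MFAP5, 3.33 for CCN5 and 1.296 for XBP1. It was lower, at -4.55 for CRISP3, -3.99 for EPB41L3, -3.66 for RASGRP1, -3.47 for FZD5, -3.46 for CPEB2, -3.46 for ZNF292, -3.34 for PSD3, -3.33 for EREG, -2.03 for KDM3A, -1.79 for PDK1, -1.71 for DDIT3, -1.63 for DDIT4, -1.13 for VEGFA and -0.57 for HIF1A. Median differences of the lists that differed were 0.91 for proliferation, 0.50 for heat shock, 0.40 for N-glycosylation, 0.33 for ER to Golgi transport, 0.28 for the interferon response, 0.22 for oxidative phosphorylation and -0.30 for PERK and ATF4 targets. With an estimated correlation all 7 lists lost their call (camera adjusted p from 0.307 to 0.514). The HIF1A difference did not pass without T47D shXBP1 replicate 2 (adjusted p = 0.0634), and the PERK list did not without T47D shCtrl replicate 1 (0.0539, median -0.162) or MDA-MB-231 shXBP1 replicate 2 (0.0733), nor with the filters on dim genes (0.0601 and 0.0648). The oxidative phosphorylation list did not pass with the mean over probe sets (0.166) or quantile normalization applied again (0.135), and its median was 0.143 without MDA-MB-231 shXBP1 replicate 1, while that of the interferon list was 0.167 without T47D shCtrl replicate 2.

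Among the 11721 probe sets unnamed here, which entered no gene or list test, 639 rose with shXBP1 in T47D and 365 in MDA-MB-231. In MDA-MB-231 787 unnamed probe sets fell, 68.3% of those called, against 50.7% of 6182 called probe sets with a name (odds ratio 2.09, Fisher's exact p = 1.19e-28, over probe sets that are not independent). In T47D the shares were 46.5% and 45.2% (Fisher's exact p = 0.423). By their means over all 8 arrays, the unnamed called probe sets were dimmer than the named ones. The median level was 6.60 against 8.24 for those called in T47D and 6.30 against 8.12 for those called in MDA-MB-231.

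HIF1 targets changed in opposite directions in the 2 lines for 7 of the 10 members changed in both. XBP1 fell in both lines (by -3.85 in the line with the smaller fall), which argues against an exchange of hairpin labels in 1 line. Under either rescaling 7 of 7 members stayed opposite. The deposited values were already quantile normalized by RMA, with array medians between 5.87 and 5.91. Such rescaling could therefore move little, and it cannot decide on scaling. Of 7 other probe sets of these genes above the median level, 5 (71.4%) showed the sign of the difference, so the choice of probe set cannot be told apart from a change of the genes with so few. Of all other genes changed in both lines 39.2% were opposite, and with 10 members the list did not pass a test against them (Fisher's exact p = 0.0565), so a split shared by all changed genes stays open. A difference between the lines in how hypoxia genes depend on XBP1 remains a hypothesis that the design cannot separate from any other difference between the 2 lines.

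Interferon response genes rose with shXBP1 in MDA-MB-231 for 14 of 28. Leukocytes in the shXBP1 cultures are argued against by 13 leukocyte markers with a median change of -0.0326, of which 0 passed in limma (2 at an unadjusted p under 0.05), with the pan-leukocyte gene PTPRC at levels of 4.05 and 4.09, although CD14 alone was at 0.75 (adjusted p = 0.107, and 0.0394 with trend and robust fitting). Of 8 other probe sets of the risen genes 7 (87.5%) were higher, which argues against a single faulty probe set per gene. Both arms carried a hairpin, so a response to hairpin RNA in any cell would be present with shCtrl too and cancel in this comparison. Whether the hairpin doses were equal was not tested. In T47D 7 of the same 28 genes rose and 2 fell, with OAS1 at 1.06 and IFIT1 at 1.00. The list median there was 0.16, with a camera adjusted p of 0.124 and a fry adjusted p of 0.0117 (higher). Single members thus rose in T47D too, but the camera test neither shows nor excludes a rise of the list against other genes. Only 1 control and 1 XBP1 hairpin group per line were used here, so an effect of the hairpin other than through XBP1 stays open. RNA quality, which was not tested, and a biological response to the loss of XBP1 stay open as well.

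Proliferation genes fell with shXBP1 in T47D for 28 of 33, and in MDA-MB-231 8 rose and 2 fell. Under the less favourable of quantile normalization applied again and median centring, 28 members were lower. These steps could move little after RMA, with array medians between 5.87 and 5.91, so they cannot decide on scaling. The choice of probe set is argued against, since 22 of 23 other probe sets of the fallen genes (95.7%) were lower. A slower growth of the T47D cultures with shXBP1, from the loss of XBP1 or from a different state of these cultures, may lie behind the pattern and was not tested.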

How the results depend on the processing

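For the overlap, all alternatives except the threshold and the fit by line were chosen after seeing the data. For the gene lists this held for all except the estimated correlation, fry, the filter at the median, the block and leaving out arrays. The cause was not tested for any change below unless the alternative itself shows it. With each probe set tested on its own, which tests 54675 items in place of 19775, the counts were 11086 in T47D, 7604 in MDA-MB-231, 9891 for the difference, 21581 between the lines and 1808 in the same direction in both lines. A minimum absolute log2 fold change of 1, which only removes genes, left 1235, 510, 1777 and 4306. With only the arrays of each line, 1897 genes passed in MDA-MB-231 (3410 in the main fit), 6147 in T47D (5746) and 646 in the same direction in both. The fit by line has fewer residual degrees of freedom, which alone would not raise the T47D count. The SD of the difference between replicates was 0.2427 and 0.2415 in the MDA-MB-231 groups against 0.2119 and 0.1763 in the T47D groups. The shared spread may therefore be too small for MDA-MB-231. Camera with an estimated correlation called 1 of 88 list tests and fry 71, against 32. The second XBP1 probe set gave -0.23 in T47D (adjusted p = 0.320) and, with the sign reversed, 0.19 in MDA-MB-231 (0.459). With the mean over probe sets IL11 in MDA-MB-231 was 0.0525 against -0.75, and HSPA5 differed between the lines by 0.70 against -0.34. Leaving out each array in turn gave 3890 to 5912 changed genes in T47D, 2063 to 2931 in MDA-MB-231 (2063 without MDA-MB-231 shCtrl replicate 1, 2152 without MDA-MB-231 shXBP1 replicate 1), 3337 to 4801 for the difference, 8587 to 9783 between the lines, 625 to 868 in the same direction in both lines (625 and 630 without T47D shXBP1 replicates 1 and 2), 348 to 647 in opposite directions, 28 to 33 list tests, and XBP1 changes of -5.33 to -4.96 in T47D and -4.07 to -3.63 in MDA-MB-231. The share of higher calls in MDA-MB-231 was 61.3%, 59.5% with median centring and 63.1% with quantile normalization applied again, and no rescaling moved a share by over 10 points. Such rescaling could move little after RMA, so it cannot decide on scaling. With line by replicate number as a replicate block, 4997 genes passed in T47D, 2416 in MDA-MB-231, 3938 for the difference and 711 in the same direction in both lines. The comparison of the lines could not be estimated with the block. The 26 list tests that passed therefore leave out that comparison and cannot be set against the 32. With the block 14 named gene results lost their call, among them VEGFA in T47D (adjusted p = 0.0507), as did the ribosomal list in T47D (0.0675), and 411 genes changed in opposite directions. Arrays with the same number did not deviate together (correlations from -0.069 to 0.0381), so the numbers were not taken as pairs. List tests were not run with trend and robust spread, a single line's arrays or array weights. Of 265 results for named genes 249 were called, and 211 of these stayed called in the same direction under each alternative run. Over 4403 gene results under alternatives, 4199 kept direction and side of the threshold, 160 lost the call (108 with 1 array left out), 42 gained it and 2 changed sign. Array signal limits dim genes, since levels near the median of 5.96 hold little above background.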

Other observations

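The families described here were formed by symbol stem alone after the data were seen, so they also hold antisense and divergent transcripts and pseudogenes named after a member, no prediction was written for them, and the example genes were chosen after their values were seen. In T47D, transcripts with the ZNF stem, mostly of zinc finger genes, were higher with shXBP1. Of 502 measured 183 rose and 20 fell (camera adjusted p = 2.06e-07 over 266 families, adjusted p = 0.870 with an estimated correlation), with ZNF680 at 2.71, ZNF506 at 2.62 and ZNF669 at 1.96. Of 48 with the ZBTB stem 24 rose and 1 fell (adjusted p = 6.27e-05, adjusted p = 0.870 with an estimated correlation), with ZBTB34 at 2.31 and ZBTB7A at 1.76, and of 19 with the KLF stem 7 rose (adjusted p = 0.0225, adjusted p = 0.870 with an estimated correlation), among them KLF3 at 3.46, KLF11 at 2.03 and KLF4 at 2.01. With quantile normalization applied again 171 ZNF, 22 ZBTB and 7 KLF transcripts rose, and with median centring 178, 22 and 7. These steps could move little after RMA, so they cannot decide on scaling for these families.

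Histone and metallothionein genes fell in T47D. Of 59 histone genes 24 fell and 1 rose (adjusted p = 6.27e-05, adjusted p = 0.870 with an estimated correlation), with the linker histone gene H1-2 at -2.52, H2BC21 at -1.84 and H2AC8 at -1.55. Of 10 genes with the MT stem 7 fell (adjusted p = 0.00664, adjusted p = 0.870 with an estimated correlation), including MT1F at -0.83, MT1X at -0.75 and MT2A at -0.77, members whose probe sets can read each other's transcripts. With quantile normalization applied again 26 histone and 6 MT genes fell, and with median centring 27 and 7, which cannot decide on scaling either. In T47D 14 of 266 families passed and 0 did with an estimated correlation (13 at an unadjusted p under 0.05). In MDA-MB-231 0 families passed in limma's camera test (20 at an unadjusted p under 0.05, lowest adjusted p = 0.401). The difference between the lines passed for the ZNF (adjusted p = 1.82e-06), ZBTB (1.06e-05), histone (0.00110), KLF (0.00179) and MT (0.00779) families. These calls were lost too, at adjusted p = 0.868 with an estimated correlation for ZNF and ZBTB, 0.916 for KLF and 0.995 for histones and MT.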
